A study of Mus musculus with 12 samples.

How the data were processed

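ATAC-seq libraries were made from hematopoietic stem cells (HSC) of mouse bone marrow, per the labels' protocols. The cells were sorted within the fraction that lacks lineage markers and carries Sca-1 and Kit. Young cells were positive for CD150 and negative for CD48, CD41 and CD34, and old cells were sorted by the same markers without the gate on CD41. Each young sample pooled 4 mice of 2.5 months, and each old sample came from 1 mouse of 18 months. The cells received a retroviral vector with GFP, either empty (mock) or expressing Pbx1, and 50000 GFP-positive cells per sample were taken on day 3. The labels name 3 biological replicates in each of 4 groups, 12 libraries in all.

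The deposited table holds raw counts, 1 whole number per library and region, with no normalization visible in the values. Per the file headers, each region has a chromosome, a start, an end, a length and a strand. Trim Galore, Bowtie2, SAMtools, Picard, MACS3 and deepTools and the genome build mm10 are named per the submitters' processing notes, with no version, parameter or step for any of them. The notes do not say which program counted the reads or whether peaks were called on pooled libraries. A second deposited file lists other values, the start and end coordinates of 185472 regions of 250 bp, of which 137216 are the regions of the count table. Of these 137216, 17869 overlap another region. Coordinates are given as in the deposited table, in mm10.

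Regions were tested in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr by group left 137212 regions, with a mean of at least 13.1 counts per library. TMM factors, a design with 1 term per group, a quasi-likelihood fit over all 12 libraries and an F test per contrast followed. P values were adjusted by Benjamini-Hochberg over all tested regions, and a region was called at an adjusted p under 0.05 with no limit on the fold. The comparisons were Pbx1 against mock in young and in old HSC, old against young in mock and in Pbx1 libraries, and the difference of the Pbx1 effect between ages as an interaction. The common dispersion was 0.0214, a biological coefficient of variation of 14.6%, with 25.0 prior degrees of freedom. Errors of log2 fold changes are standard errors derived from the F statistic, and levels are TMM-normalised CPM with the SD over 3 libraries.

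Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 represents, restricted to protein-coding genes on the autosomes and the X chromosome. The table gives gene spans without strand, transcripts or exons. The plan called for the nearest transcription start site and for promoters, which such spans do not give. Each region was therefore assigned to the nearest gene span within 50 kb (inside the span counts as no distance), with ties settled by the nearer gene end, and regions within 1 kb of either end of a gene took the place of promoters. GenomicRanges 1.54.1 assigned 88.2% of the regions, and 17.7% of the regions lay within 1 kb of a gene end. Counts of all regions of a gene were summed, which gave 17203 genes, and tested as the regions were. A sum mixes promoters, enhancers and other open sites of a gene, so that it measures accessibility around the gene and not its expression.

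Before the data were examined, 14 gene lists with 302 distinct genes were fixed, and 298 of these genes matched the gene table. They cover HSC identity, genes known to rise with HSC age, megakaryocytes and platelets, neutrophils with monocytes and macrophages, lymphoid cells, erythroid cells, mast cells with basophils and eosinophils, stroma with endothelium, Hox and TALE homeobox genes, the cell cycle, the interferon response, NF-kB and inflammation, AP-1 and immediate early genes, and TGF-beta and BMP signalling. Some genes stand in more than 1 list. Each list was tested against all other genes with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and again with a correlation estimated from the data, and p values were adjusted over the 14 lists of a contrast. A rotation test (fry) of each list is kept in the tables. With the preset correlation, other splits of the same libraries also called lists, as given at the end. A list call alone therefore does not set the real groups apart. Members were counted at an adjusted p under 0.05 over all genes and also adjusted over the list alone. The location of called regions was compared by a two-sided Fisher exact test against all other tested regions, adjusted over the family.

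The rule for named genes was set at that time too, with start sites where gene spans are now used. It takes, per contrast and direction, up to 8 called regions with the largest fold, an average level at or above the median of tested regions and no overlap between the libraries of both groups, at most 1 per gene. For the interaction it takes up to 4 per direction without the condition on overlap. From each list it takes up to 3 called members with the largest fold, or the member with the lowest p where none was called, and Pbx1 always.

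The libraries held 4822017 to 23684266 counts. On counts simulated from the average level and dispersion of each region, with known changes added to the young Pbx1 libraries, the region test for Pbx1 against mock in young HSC recovered 8.96% of changes of 1.5-fold, 37.3% of 2-fold and 80.3% of 4-fold. Of its calls on 137212 regions, 4.55% were false (4 regions). The gene test for the same comparison on 17203 genes recovered 73.1%, 92.5% and 100% of these sizes, with 6.35% false calls (12 genes). Each simulation changed only 67, 67 and 66 features of these sizes. The adjustment depends on how many features change, and the data gave many more calls. These shares therefore do not measure recovery in the data. Reads without molecular identifiers are not independent molecules, so the 95% interval given for a ratio (exact binomial, where a group held 3 counts or fewer) covers counting error only. The correlation of the Pbx1 effect in old HSC with the age effect was set beside 8 simulations with no Pbx1 effect, drawn from the fitted means and dispersions, since both comparisons use the old mock libraries.

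Alternatives were other scalings (DESeq2 size factors, total counts, TMMwsp, cyclic loess with voom), DESeq2 1.42.0 with its Wald test, no filter or a stricter one, only the groups compared, the replicate number as a block, an adjusted p under 0.01, a fold limit, other gene distances, an estimated correlation and the omission of each library in turn. Regions without overlap, thinning to the smallest library, the share of counts near gene ends as a covariate, autosomes only and the assignment to the nearest gene end were added after the data were seen. Left out were motif tests, since no genome sequence was used here, the separation of Pbx1 exons from other Pbx1 regions, and the listed regions without counts.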

Results

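Open chromatin was measured by ATAC-seq in HSC from young and old mice, 3 days after transduction with an empty vector (mock) or with a vector expressing Pbx1, a TALE homeobox transcription factor. The series title places Pbx1 at a hub of HSC ageing, and the design asks what added Pbx1 does to HSC of each age and how old HSC differ from young. Each of the 4 groups held 3 libraries, and young and old cells were sorted with different gates, since CD41 was excluded in young cells only. Every comparison of age carries this difference.

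The libraries held 13473599, 12257568 and 4822017 counts in young mock, 23684266, 6253442 and 16974041 in young Pbx1, 16356848, 20066578 and 15407235 in old mock, and 8807674, 13362172 and 17286873 in old Pbx1. The share of counts within 1 kb of a gene end was 38.5% ± 1.01 (SD, n = 3) in young mock, 37.2% ± 0.345 in young Pbx1, 37.8% ± 0.847 in old mock and 37.1% ± 1.25 in old Pbx1. The first principal component of log2 CPM held 34.4% of the variance. It placed young mock at -162 to -97.2, young Pbx1 at -80.6 to -55.8, old mock at 47.7 to 69.2 and old Pbx1 at 99.5 to 164, with old Pbx1 replicate 2 farthest out. Across regions, which are not independent replicates, libraries of 1 group correlated with r of 0.902 to 0.969 and libraries of different groups with r of 0.779 to 0.949.

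The Pbx1 gene itself, with 29 regions, did not pass the test for Pbx1 against mock at either age. Its regions summed to 232 CPM ± 17.2 (SD, n = 3) in young mock, 224 ± 9.18 in young Pbx1, 247 ± 14.97 in old mock and 281 ± 59.2 in old Pbx1. The log2 fold change was -0.046 ± 0.095 (SE, adjusted p = 0.895) in young and 0.19 ± 0.093 (adjusted p = 0.294) in old HSC. Old against young gave 0.098 ± 0.094 (adjusted p = 0.537) in mock libraries. In Pbx1 libraries the gene rose by 0.33 ± 0.094 (adjusted p = 0.0135), and this call ended without young Pbx1 replicate 3 (0.30, adjusted p = 0.068) or old Pbx1 replicate 2 (0.14, adjusted p = 0.072). Old Pbx1 replicate 2 held 349 CPM at the gene, against 243 and 250 in the other old Pbx1 libraries. The regions that cover exons could not be separated, so reads of the vector were not counted apart.

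Pbx1 against mock in young HSC asks which sites the factor opened or closed in young cells. Each region is named for its nearest gene and lies inside that gene unless a distance is given, and other regions of the gene can differ from it. Among the named regions that rose, 1 inside Naa35 had the largest log2 fold change, 3.97 ± 0.41 (SE), from 0.264 to 3.70 CPM. The region of Arfgef1, which encodes an exchange factor for small GTPases of the Golgi (chromosome 1, 10210866 to 10211115), went from 2.38 CPM ± 0.589 (SD, n = 3) to 18.6 ± 0.808, a log2 fold change of 2.96 ± 0.18 (SE, adjusted p = 2.31e-12). The region of Arhgap26, a GTPase-activating protein (chromosome 18, 39284227 to 39284476), went from 0.623 ± 0.207 to 5.97 ± 1.28 CPM, with 3.13 ± 0.31 (adjusted p = 5.07e-08). Mpo encodes the myeloperoxidase of neutrophil granules, and a region 97 bp from it (chromosome 11, 87793437 to 87793686) fell from 6.63 ± 2.34 to 1.98 ± 0.161 CPM, by 1.69 ± 0.28 (adjusted p = 0.000213). Of 137212 regions tested, 3402 rose and 542 fell, so that 86.3% of the called regions rose.

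Further regions that rose in young HSC were nearest to Mdga2 (2.88 ± 0.37), Dock7 (2.85 ± 0.40, 13.1 kb away), Itprid2 (2.80 ± 0.47, 13.5 kb), Hspbp1 (2.79 ± 0.40) and Vamp9 (2.79 ± 0.40, 37.0 kb), as log2 fold change ± SE. Regions that fell were nearest to Shroom3 (-1.79 ± 0.22), Atp1a3 (-1.62 ± 0.24, 0.61 kb away), Vwce (-1.53 ± 0.21), Btbd9 (-1.53 ± 0.32), Pef1 (-1.43 ± 0.29), Rreb1 (-1.39 ± 0.29) and Pim1 (-1.35 ± 0.35, 43.2 kb). Another region of Btbd9 rose. Regions that rose lay within 1 kb of a gene end in 4.06% of cases, against 18.0% of the other tested regions (odds ratio 0.19), and regions that fell in 5.72% (odds ratio 0.28). The count of 3944 called regions was 2172 without young mock replicate 1, 2235 without young mock replicate 2, 2199 without young Pbx1 replicate 1, 2126 without young Pbx1 replicate 3 and 6482 without old Pbx1 replicate 2. It was 6285 when only the young libraries were fitted. Pef1 did not pass without young mock replicate 2 or young Pbx1 replicate 3 (adjusted p up to 0.084), nor Pim1 without any 1 of the young mock libraries or young Pbx1 replicates 1 or 3 (adjusted p up to 0.215).

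**Figure D1:**
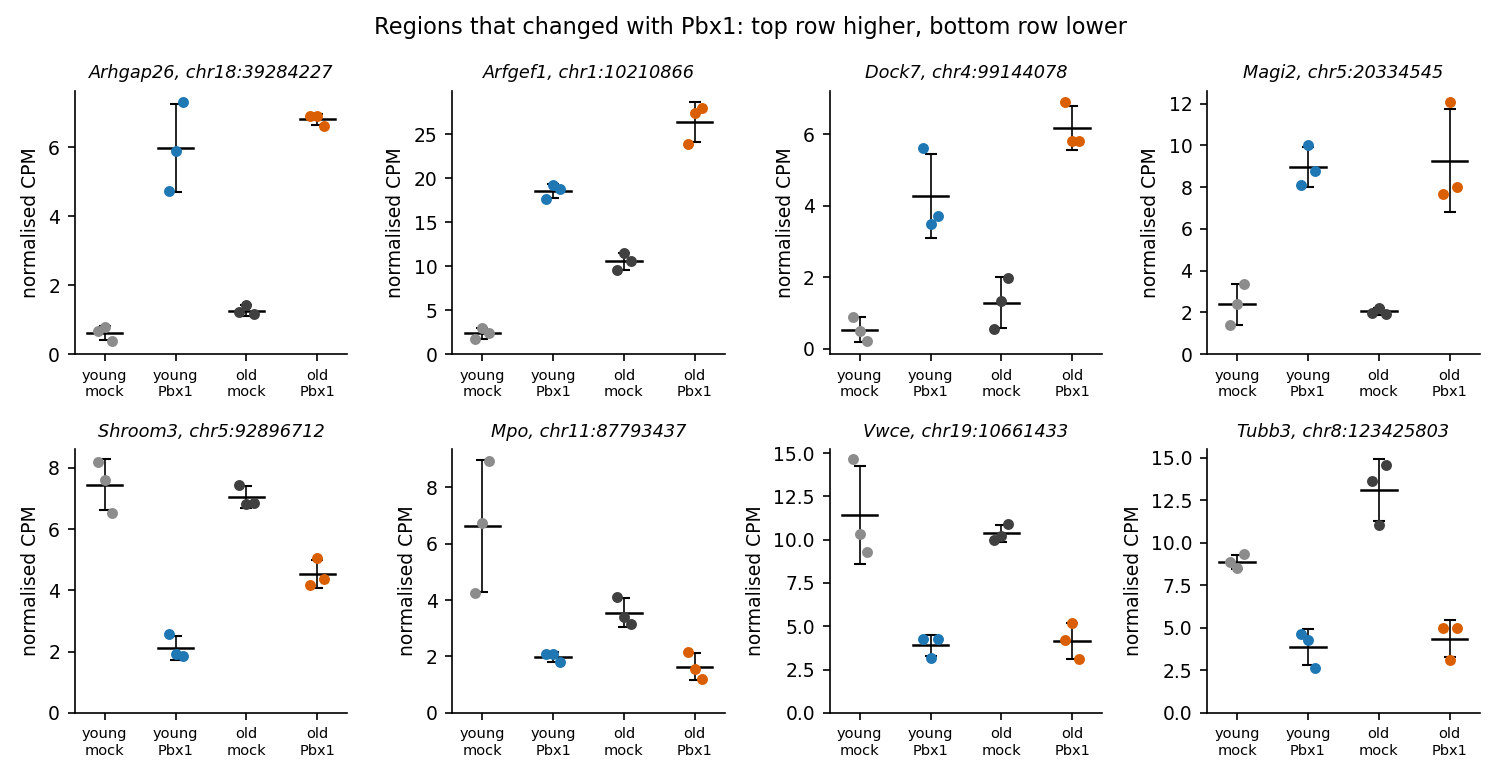
Normalised CPM at 8 regions named for Pbx1 against mock, with each library as a point and bars at the mean ± SD of 3 libraries per group. Regions nearest to Arhgap26, Arfgef1, Dock7 and Magi2 were higher with Pbx1 at both ages, and regions nearest to Shroom3, Mpo, Vwce and Tubb3 were lower.

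Summed over all regions of a gene, 414 genes rose and 68 fell in young HSC among 17203. Of 30 genes known to rise with HSC age, 4 rose and none fell, also adjusted over the list alone. They included Nupr1, a stress-responsive transcriptional regulator (1.24 ± 0.11, adjusted p = 4.95e-07), Runx1t1, a transcriptional corepressor (0.50 ± 0.084, adjusted p = 0.00115), and Cavin2, a protein of caveolae (0.67 ± 0.14, adjusted p = 0.00913). The list test gave an adjusted p of 0.0128, and adjusted p = 0.553 with an estimated correlation. With the preset correlation, other splits of the young libraries called up to 5 lists. Of 23 HSC identity genes, 4 rose and none fell (5 adjusted over the list alone), with Esam, an adhesion molecule of HSC, at 0.40 ± 0.097 Lmo2, a cofactor of blood transcription complexes, at 0.25 ± 0.054 and Hlf, a transcription factor, at 0.24 ± 0.067. The list had an adjusted p of 0.0128, and adjusted p = 0.425 with an estimated correlation. Esam did not pass without young mock replicate 1 (adjusted p = 0.169) or 3 or any 1 young Pbx1 library, nor Cavin2 without young mock replicates 2 (0.062) or 3 or young Pbx1 replicate 2. Lmo2 did not pass without young Pbx1 replicate 1 (0.101) or 3, or with regions within 5 kb only (0.50), and Runx1t1 did not pass with the nearest gene end (0.066). Hlf did not pass in 9 of 12 omissions of 1 library (adjusted p up to 0.274) or with DESeq2 size factors (0.0510).

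Of 19 megakaryocyte and platelet genes, 4 rose and none fell in young HSC (5 and 1 adjusted over the list alone), among them Pf4, a platelet chemokine, at 0.31 ± 0.084, F2rl2, a thrombin receptor, at 0.30 ± 0.080 and Gp9, a platelet glycoprotein, at 0.28 ± 0.067. The list had an adjusted p of 0.0128, and adjusted p = 0.553 with an estimated correlation. Gp9 did not pass without young mock replicates 1 or 2 or young Pbx1 replicates 1 or 3 (adjusted p up to 0.144). Pf4 did not pass in 8 of 12 omissions (up to 0.179), nor F2rl2 in 9 (up to 0.160) or with the nearest gene end (0.420). None of Esam, Lmo2, Hlf and Kit, the HSC identity genes that rose, passed without young Pbx1 replicate 1 or without young Pbx1 replicate 3. All 3 list calls ended without young mock replicate 1 (adjusted p = 0.0735), and that of megakaryocytes also without young mock replicate 3 (0.0892). The 482 called genes were 198 without young mock replicate 1, 286 without young mock replicate 2, 230, 261 and 238 without young Pbx1 replicates 1, 2 and 3, and 1091 without old Pbx1 replicate 2.

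The other 11 lists did not pass in young HSC. Mpo fell by 1.11 ± 0.18 (adjusted p = 0.000678) as the only called member of 22 neutrophil, monocyte and macrophage genes, where 1 rose and 1 fell adjusted over the list alone (list adjusted p = 0.861). Eng, a co-receptor for TGF-beta, rose by 0.46 ± 0.087 (adjusted p = 0.00319), and 2 of 20 TGF-beta and BMP genes rose by either adjustment (list adjusted p = 0.117). The other, Smad7, at 0.24 ± 0.065, did not pass in 9 of 12 omissions (adjusted p up to 0.208), with regions within 5 kb only (0.193) or with DESeq2 size factors (0.0531). Trp53 fell by 0.30 ± 0.078 among 27 cell cycle genes, Cxcl12 rose by 0.64 ± 0.16 among 15 stroma genes, and Kit, the receptor of stem cell factor, by 0.24 ± 0.064 among 13 mast cell genes. Adjusted over the list alone, the counts were 0 up and 1 down for the cell cycle, 2 and 1 for stroma and 1 and 1 for mast cells (list adjusted p = 0.419, adjusted p = 0.385 and adjusted p = 0.861). Trp53 and Kit did not pass without any 1 of the young libraries or without old mock replicates 1 or 3 (adjusted p up to 0.152 and 0.209), Kit not without old mock replicate 2, and Cxcl12 not without young mock replicate 2 (0.172) or any 1 young Pbx1 library. Kit did not pass with regions within 5 kb only (0.220), nor Cxcl12 with 5 kb (0.35, adjusted p = 0.50) or 500 kb (0.13, adjusted p = 0.543). The NF-kB list passed with the replicate block (adjusted p = 0.0327), without young mock replicate 2 (0.0141) or without old Pbx1 replicate 2 (0.0379), and the TGF-beta list without young mock replicate 2 (0.0141). No member passed over all genes in the lymphoid list (Bcl11a 0.24, adjusted p = 0.0687, list adjusted p = 0.385), the erythroid list (Gata1 -0.47, adjusted p = 0.115, list adjusted p = 0.0799), Hox and TALE (Hoxa10 0.27, adjusted p = 0.119, list adjusted p = 0.861), interferon (Rsad2 -0.28, adjusted p = 0.0969, list adjusted p = 0.690), NF-kB (Il1r1 0.27, adjusted p = 0.0747, list adjusted p = 0.0799) or AP-1 (Egr3 0.22, adjusted p = 0.220, list adjusted p = 0.599). The 2 genes that rose adjusted over the lymphoid list alone were the only ones of these 6 lists. With the replicate block Bcl11a (adjusted p = 0.0223), Gata1 (0.0480) and Il1r1 (0.0322) passed, and Bcl11a also with regions within 500 kb (0.00398). The list medians of the neutrophil genes (0.034) and the interferon genes had the opposite sign to their tests, which pointed down.

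Pbx1 against mock in old HSC asks the same of old cells. A region 18.4 kb from Fzd9, a Wnt receptor (chromosome 5, 135269455 to 135269704), went from 1.76 CPM in old mock to 8.44 in old Pbx1, a log2 fold change of 2.27 ± 0.24 (adjusted p = 6.19e-07, n = 3 libraries per group, edgeR). A region inside Magi2, a scaffold protein of cell junctions (chromosome 5, 20334545 to 20334794), went from 2.05 to 9.26 CPM, by 2.17 ± 0.23 (adjusted p = 7.85e-07). The region of Arhgap26 rose by 2.41 ± 0.25 (adjusted p = 5.45e-07). Of the other regions of Magi2 and of Arhgap26, 3 rose and 1 fell in each gene. A region 3.79 kb from Tubb3, a tubulin (chromosome 8, 123425803 to 123426052), fell from 13.1 to 4.35 CPM, by 1.59 ± 0.20 (adjusted p = 1.01e-05). In all, 3730 regions rose and 769 fell, so that 82.9% of the called regions rose, and 71.6% with total counts as the scaling.

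Other regions that rose in old HSC were nearest to Nedd4 (2.29 ± 0.32), Itprid2 (2.28 ± 0.34, 13.5 kb away), Dock7 (2.25 ± 0.31, 13.1 kb), St6galnac5 (2.14 ± 0.31) and Vamp9 (2.13 ± 0.34, 37.0 kb). Regions that fell were nearest to Gm21297 (-1.85 ± 0.32), Cacng3 (-1.73 ± 0.25), Ethe1 (-1.70 ± 0.31), Lcorl (-1.68 ± 0.29), Ano1 (-1.66 ± 0.29), Vwce (-1.66 ± 0.24) and Dapk2 (-1.62 ± 0.34). Of the other regions of Ano1, 2 rose and 1 fell. Of the regions that rose, 3.86% lay within 1 kb of a gene end, against 18.1% of the other tested regions (odds ratio 0.18), and of those that fell 8.71% (odds ratio 0.44). All of these named regions passed in every omission of 1 library. The count of 4499 was 1680 without old mock replicate 1, 1984 without old mock replicate 3 and 2725 without old Pbx1 replicate 2. It was 2068 when only the old libraries were fitted.

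At gene level, 387 genes rose and 156 fell in old HSC. Of 23 HSC identity genes, 4 rose and none fell (6 adjusted over the list alone), among them Procr, a surface marker of HSC (0.54 ± 0.083, adjusted p = 0.000915), Mllt3, a regulator of HSC maintenance (0.48 ± 0.090, adjusted p = 0.00406), and Kit (0.34 ± 0.062, adjusted p = 0.00324). The list test gave an adjusted p of 9.82e-05, and adjusted p = 0.115 with an estimated correlation. With the preset correlation, other splits of the old libraries called up to 7 lists. Of 22 NF-kB and inflammatory genes, 2 rose and none fell (10 adjusted over the list alone), namely Ccl4, a chemokine (0.88 ± 0.17, adjusted p = 0.00558), and Il6ra (0.29, adjusted p = 0.0244). That list had an adjusted p of 2.35e-05, and adjusted p = 0.526 with an estimated correlation. In old Pbx1 replicate 2 these genes deviated from the other old Pbx1 libraries by a median log2 of 0.22 (percentile 99.99 of random lists), and without that library the list had an adjusted p of 0.0176. Il6ra did not pass without old mock replicate 1 or 3 or old Pbx1 replicate 2 (adjusted p up to 0.143). Of 30 genes known to rise with HSC age, 3 rose and none fell by either adjustment, with Nupr1 at 0.66 ± 0.093, Cavin2 at 0.46 ± 0.12 and Runx1t1 at 0.45 ± 0.079. Cavin2 did not pass in 6 of 12 omissions (adjusted p up to 0.199). The list had an adjusted p of 0.0172, and adjusted p = 0.526 with an estimated correlation, and did not pass without old mock replicate 1 (0.0722), old mock replicate 3 (0.0502) or old Pbx1 replicate 2 (0.345), where these genes deviated by a median log2 of 0.17 (percentile 99.96). Procr did not pass with regions within 5 kb only (adjusted p = 0.523), nor Mllt3 with the nearest gene end (0.079).

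The other 11 lists did not pass in old HSC, though 4 of them passed in some settings. The lymphoid list passed with the replicate block (adjusted p = 0.0425), with regions within 500 kb (0.0438), with the nearest gene end (0.0449), without old mock replicate 2 (0.0362) and without old Pbx1 replicate 3 (0.0201). Without these same libraries in turn, the megakaryocyte list (0.0200 and 0.0472) and the cell cycle list (0.0362 and 0.0472) passed too, and the AP-1 list passed without old Pbx1 replicate 1 (0.0168) or 3 (0.0472). Mpo fell by 1.19 ± 0.19 (adjusted p = 0.00122), the only called member of 22 neutrophil, monocyte and macrophage genes (list adjusted p = 0.394). Dntt, the terminal transferase of lymphoid precursors, rose by 0.46 ± 0.090, and Flt3, a receptor of early progenitors, rose by 0.34 ± 0.065. They were the 2 called members of 19 lymphoid genes, where 6 rose and 1 fell adjusted over the list alone (list adjusted p = 0.0632). Of 19 megakaryocyte genes, 2 rose by either adjustment (list adjusted p = 0.176), with Treml1 at 0.60 ± 0.15 and Rab27b at 0.23 ± 0.060. Rab27b did not pass in 8 of 12 omissions (adjusted p up to 0.223) or with the nearest gene end (0.0691). Of 20 TGF-beta and BMP genes, 2 rose by either adjustment (list adjusted p = 0.198), with Eng at 0.38 ± 0.080 and Smad7 at 0.25 ± 0.063. Smad7 did not pass in 3 of 12 omissions (adjusted p up to 0.137) or with regions within 5 kb only (0.0937). Of 13 mast cell genes, 2 rose (2 rose and 1 fell adjusted over the list alone), with Ms4a2 at 0.58 ± 0.13 (list adjusted p = 0.554, with a median of -0.0078 and a test pointing up). No member passed over all genes in the erythroid list (Epor -0.19, adjusted p = 0.106, list adjusted p = 0.394), stroma (Pecam1 0.27, adjusted p = 0.0669, list adjusted p = 0.359), Hox and TALE (Hoxa7 0.31, adjusted p = 0.134, list adjusted p = 0.394), cell cycle (Mcm6 -0.25, adjusted p = 0.114, list adjusted p = 0.123), interferon (Ifitm1 -0.30, adjusted p = 0.0884, list adjusted p = 0.511) or AP-1 (Junb 0.20, adjusted p = 0.0891, list adjusted p = 0.123). With the replicate block Pecam1 (adjusted p = 0.0185), Ifitm1 (0.0202) and Junb (0.0339) passed. Adjusted over the list alone, 1 stroma gene rose, and 2 interferon genes rose and 1 fell. Eng and Ms4a2 did not pass without old mock replicate 1 or 3 (adjusted p up to 0.060 and 0.099), nor Treml1 without these or old Pbx1 replicate 2 (up to 0.158). The 543 called genes were 166 without old mock replicate 1, 357 without old mock replicate 2, 194 without old mock replicate 3, 954 without old Pbx1 replicate 1 and 1015 without old Pbx1 replicate 3.

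Many regions responded to Pbx1 at both ages. Regions nearest to Arhgap26, Dock7, Itprid2 and Vamp9 rose in both, and 1634 regions rose in both where 92.5 would be shared by chance. A further 110 fell in both, where chance gives 3.04, and none was called in opposite directions. Across all tested regions, the Pbx1 effects in young and old HSC, which share no library, had r = 0.44 and rho = 0.36 (across regions, which are not independent replicates). Of the regions called in young HSC, 96.2% had the same sign in old HSC, and of those called in old HSC, 93.5% had the same sign in young.

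**Figure D2:**
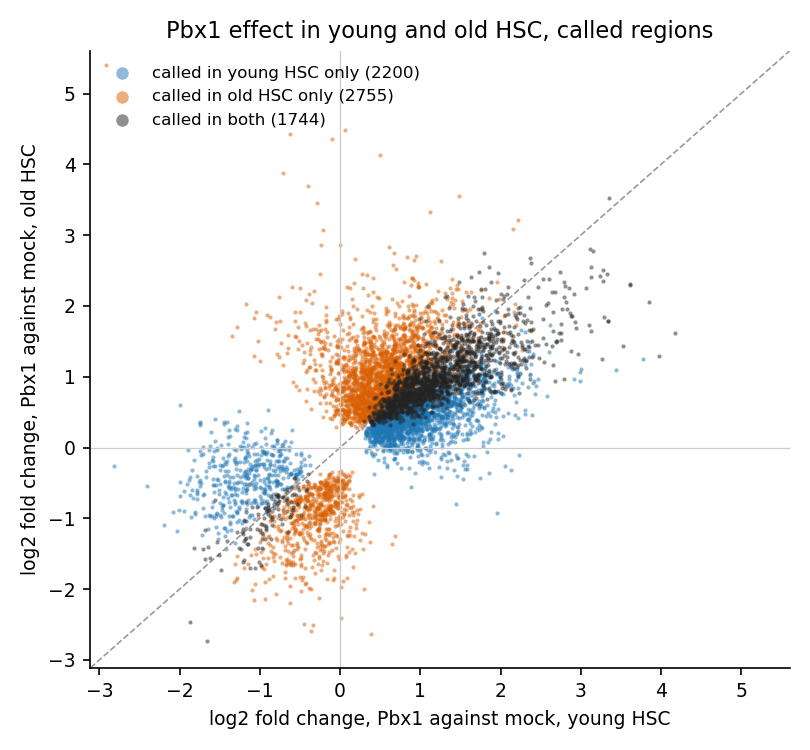
Log2 fold change of Pbx1 against mock in old HSC (vertical) by that in young HSC (horizontal), for the 6699 regions called at either age. Of these, 1744 were called at both ages, 2200 in young HSC only and 2755 in old HSC only, and r among them was 0.62.

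The difference of the Pbx1 effect between ages passed at 1 region, that of Arfgef1. It went from 2.38 CPM to 18.6 in young HSC and from 10.6 CPM ± 0.966 (SD, n = 3) to 26.4 ± 2.23 in old HSC. The fold change was thus smaller in old HSC, with a log2 difference of -1.64 ± 0.24 (SE, adjusted p = 0.00803). The rise in CPM was of similar size at both ages, from a higher level in old mock. At an unadjusted p under 0.05, edgeR gave 7736 regions, and DESeq2 called 10 regions and voom with cyclic loess 0. The Arfgef1 difference did not pass without young mock replicate 1 (adjusted p = 0.25), young Pbx1 replicate 3 (0.058) or old mock replicate 2 (0.066), and the count was 2 without old mock replicate 3, 19 without old Pbx1 replicate 2 and 21 without old Pbx1 replicate 3. No gene passed in edgeR (1089 at an unadjusted p under 0.05). None of the 14 lists passed (lowest adjusted p = 0.12, NF-kB). Nupr1 had a difference of -0.58 ± 0.14, with adjusted p = 0.582 over all genes and 0.0152 adjusted over the list alone. The members with the lowest p of the other 13 lists did not pass either (adjusted p of 0.751 or more over all genes): Hoxa7 0.43, Ms4a2 0.40, Procr 0.37, Rsad2 0.36, Tlr2 0.35, Dntt 0.29, Car2 0.29, Irf8 -0.26, Egr3 -0.29, Id1 -0.31, Ccnd1 -0.33, Gp1bb -0.38 and Cxcl12 -0.50.

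Old against young HSC in mock libraries asks how age, with the gate and the pooling of mice, changed open chromatin. A region 26.4 kb from Wars2, a mitochondrial tryptophan tRNA ligase (chromosome 3, 99113463 to 99113712), rose from 0.825 CPM to 16.0, a log2 fold change of 4.24 ± 0.30 (SE, n = 3 libraries per group), and a region inside Rbfox1, a splicing regulator (chromosome 16, 6321851 to 6322100), from 0.954 to 13.1 CPM. A region 37.2 kb from Hmga2, a chromatin protein gene (chromosome 10, 120323854 to 120324103), fell from 19.3 to 4.03 CPM, by 2.24 ± 0.20. Of the other regions assigned to Hmga2, 5 rose and 2 fell, and the sum of all 39 did not pass (0.030 ± 0.093, adjusted p = 0.866). A region inside Gnas, a G protein subunit (chromosome 2, 174295418 to 174295667), fell from 7.45 to 0.794 CPM, by 3.25 ± 0.30. In all, 7672 regions rose and 6215 fell, but 6982 and 7026 with cyclic loess and voom, where more fell than rose. Of the regions that rose, 11.4% lay within 1 kb of a gene end (odds ratio 0.58), and of those that fell 10.7% (odds ratio 0.55).

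Other regions higher in old mock HSC were nearest to Pcdh15 (5.51 ± 0.44, from 0.103 to 6.25 CPM), Pls3 (5.14 ± 0.49, 44.6 kb away), Kcnb2 (4.33 ± 0.40), Xirp2 (4.20 ± 0.42, 7.17 kb), Dpy19l3 (3.83 ± 0.38) and Thsd4 (3.75 ± 0.47). Regions that fell were nearest to Tnfrsf9 (-2.65 ± 0.23), Npc2 (-2.53 ± 0.33, 3.56 kb away), Dntt (-2.41 ± 0.33), Plekha2 (-2.36 ± 0.20), Zbtb49 (-2.23 ± 0.37) and Fgf6 (-2.22 ± 0.31, 19.8 kb). Of the other regions of Rbfox1, 4 rose and 1 fell, and of those of Thsd4, 11 rose and 1 fell. The count of 13887 was 8976 without young mock replicate 1, 9073 without young mock replicate 2 and 7827 without old mock replicate 2. All of these named regions passed in every omission of 1 library.

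X-linked loci separated every old library from every young one, and were chosen after their values were seen. Firre, a noncoding RNA gene of the X chromosome (X, 50563120 to 50635321, 35 regions), held 25.0 to 35.5 CPM in the 6 young libraries and 231 to 260 in the 6 old ones. Xist, the RNA that coats the inactive X chromosome (3 regions), held 2.87 to 6.54 CPM in young and 19.1 to 22.7 in old libraries. 4933407K13Rik, which lies at the Dxz4 repeat of the X chromosome (X, 75725458 to 75764699, 24 regions), held 15.8 to 18.4 CPM in young and 86.3 to 111 in old libraries. The regions named for Pls3 lie at the 4933407K13Rik locus, since only protein-coding genes were used to name regions. The labels give no sex of the mice.

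**Figure D3:**
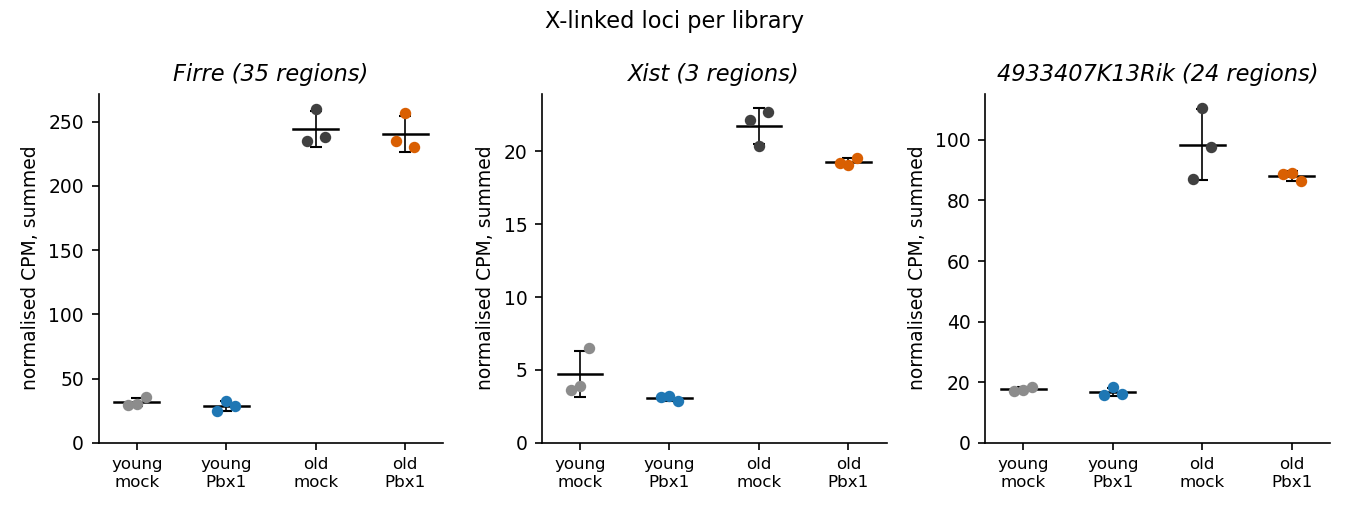
Summed CPM at Firre, Xist and 4933407K13Rik in each of 12 libraries, with each library as a point and bars at the mean ± SD of 3 libraries per group. The old libraries lie above all young libraries at each locus, with a ratio of means of 8.03 at Firre, 5.28 at Xist and 5.41 at 4933407K13Rik.

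At gene level, 1524 genes rose and 1130 fell with age in mock libraries. Of 30 genes known to rise with HSC age, 12 rose and none fell (17 adjusted over the list alone), among them Nupr1 (1.52 ± 0.11, adjusted p = 6.07e-09), Cavin2 (1.32 ± 0.14) and Clca3a1 (1.10 ± 0.24). The list had an adjusted p of 2.77e-09, and adjusted p = 0.0657 with an estimated correlation. Of 23 HSC identity genes, 9 rose and none fell (12 adjusted over the list alone), with Esam at 0.80 ± 0.095, Mpl, the thrombopoietin receptor, at 0.76 ± 0.11 and Hoxb5 at 0.60 ± 0.15, which did not pass without young mock replicate 1 (adjusted p = 0.0996). Of 26 Hox and TALE genes, 11 rose and none fell (12 adjusted over the list alone), with Hoxb2 at 1.04 ± 0.12, Hoxb6 at 0.89 ± 0.15 and Hoxa10 at 0.86 ± 0.087. These 2 lists had adjusted p of 2.21e-07 and 2.45e-06, and held with an estimated correlation (adjusted p = 0.0300 and 0.0313). Of 19 megakaryocyte genes, 6 rose and none fell (7 adjusted over the list alone), with Tubb1, the tubulin of platelets, at 0.94 ± 0.14 (list adjusted p = 5.83e-05, and adjusted p = 0.124 with an estimated correlation). Gp1bb, at 0.36 ± 0.12, did not pass in 6 of 12 omissions (adjusted p up to 0.226) or with the nearest gene end (0.538).

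Of 20 TGF-beta and BMP genes, 6 rose and none fell with age in mock libraries (9 adjusted over the list alone), with Bmpr1a, a BMP receptor, at 1.60 ± 0.13, Eng at 0.45 ± 0.086 and Skil at 0.29 ± 0.071 (list adjusted p = 0.000601, and adjusted p = 0.0953 with an estimated correlation). Of 20 AP-1 and immediate early genes, 7 rose and 1 fell (9 and 2 adjusted over the list alone), with Junb at 0.37 ± 0.067, Ier2 at 0.36 ± 0.057 and Egr3 at 0.36 ± 0.086 (list adjusted p = 0.0101, and adjusted p = 0.456 with an estimated correlation). Of 19 interferon genes, 5 rose and none fell by either adjustment, with Isg15 at 0.90 ± 0.25, Ifit1 at 0.66 ± 0.19 and Ifit2 at 0.30 ± 0.076 (list adjusted p = 0.0208, and adjusted p = 0.0953 with an estimated correlation). Of 22 NF-kB genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone), with Bcl3, a co-regulator of NF-kB, at 0.67 ± 0.081, Ccl3, a chemokine, at 0.48 ± 0.11 and Ptgs2, a cyclooxygenase, at -0.46 ± 0.12 (list adjusted p = 0.0428, and adjusted p = 0.465 with an estimated correlation). With regions within 5 kb only Ccl3 had the opposite sign (-0.18, adjusted p = 0.736). The AP-1 list did not pass without young mock replicate 3 (adjusted p = 0.0622). The NF-kB list did not pass without young mock replicates 1 (0.101) or 3 (0.0622), young Pbx1 replicate 2 (0.0511) or old mock replicate 2 (0.0592), or with the nearest gene end (0.0609). Isg15 did not pass without young mock replicates 1 or 3 or old mock replicates 2 or 3 (adjusted p up to 0.077), nor Ifit2 without old mock replicate 2 (0.057). Ifit1 did not pass in 4 of 12 omissions (adjusted p up to 0.103) or with the nearest gene end (0.440), nor Ptgs2 in 2 (up to 0.0755), with regions within 5 kb (0.129) or with 500 kb (0.0657).

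The other 6 lists did not pass with age in mock libraries, though the lymphoid list did without old mock replicate 2 (adjusted p = 0.0492). Ctsg, the protease cathepsin G of neutrophils, fell by 1.87 ± 0.24, S100a8 by 1.03 ± 0.31 and Mpo by 0.78 ± 0.17 among 22 neutrophil genes, where 3 rose and 3 fell (4 and 4 adjusted over the list alone, list adjusted p = 0.812, median 0.0042 with a test pointing down). Mcpt8, a protease of basophils, fell by 1.81 ± 0.22 among 13 mast cell genes, where 1 rose and 2 fell by either adjustment (list adjusted p = 0.261), with Gata2 at 0.36 ± 0.062 and Mitf at -0.24 ± 0.064. Of 19 lymphoid genes, 2 rose and 5 fell (3 and 9 adjusted over the list alone, list adjusted p = 0.0801), with Cd3e at -0.67 ± 0.21, Bcl11b at -0.43 ± 0.14 and Dntt at -0.37 ± 0.092. Of 27 cell cycle genes, 2 rose and 7 fell by either adjustment (list adjusted p = 0.237), with the replication helicase genes Mcm2 at -0.49 ± 0.091, Mcm5 at -0.48 ± 0.070 and Mcm6 at -0.47 ± 0.084. Of 16 erythroid genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone, list adjusted p = 0.238), with Epor, the erythropoietin receptor, at 0.57 ± 0.068, Hbb-bt at 0.54 ± 0.099 and Tfrc at -0.28 ± 0.073. Of 15 stroma genes, 3 rose and 1 fell by either adjustment (list adjusted p = 0.397, median -0.0036 with a test pointing up), with Emcn, an endothelial surface protein, at 0.54 ± 0.15, Col1a2, a collagen, at 0.45 ± 0.099 and Pecam1 at 0.33 ± 0.081. With regions within 5 kb only Col1a2 had the opposite sign (-0.11, adjusted p = 0.710). Emcn did not pass without young mock replicate 1 or old mock replicate 2 (adjusted p up to 0.144), nor Dntt without young mock replicate 2 (0.057) or with regions within 5 kb only (0.121). Of the others named here, S100a8 did not pass in 4 of 12 omissions (adjusted p up to 0.147), Cd3e in 5 (up to 0.0930), Tfrc in 2 (up to 0.0698) and Pecam1 in 1 (0.0568). Bcl11b did not pass in 8 (up to 0.168), with regions within 5 kb (0.0699) or with 500 kb (0.318), nor Mitf in 2 (up to 0.0622) or with the nearest gene end (0.375). Of the 41 called members that the rule names for this comparison, 27 passed in every omission. The 2654 called genes were 1735 without young mock replicate 1 and 1445 without old mock replicate 2.

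Old against young HSC in Pbx1 libraries asks the same with the factor added. The region of Wars2 rose by 4.22 ± 0.26 (SE, n = 3 libraries per group) and that of Rbfox1 by 4.49 ± 0.34, while the region inside Gnas fell by 3.32 ± 0.30 and the region 37.2 kb from Hmga2 by 2.81 ± 0.23. Of the other regions assigned to Hmga2, 8 rose and 2 fell, of those of Gnas 1 rose and 2 fell, and of those of Rbfox1 7 rose and 2 fell. A region 5.01 kb from Adgrg2, an adhesion receptor (X, 160385055 to 160385304), rose by 3.57 ± 0.27. This region is X-linked, and the labels give no sex of the mice. A region inside Tnfrsf9, a receptor of the TNF family, fell by 3.12 ± 0.19. The region of Pcdh15 held 3 counts in young Pbx1 and 260 in old Pbx1, a ratio of 106 (95% interval 35.8 to 516). Other regions that rose were nearest to Xirp2 (5.14 ± 0.45, 7.17 kb away), Pls3 (4.98 ± 0.35, 40.8 kb), Kcnb2 (3.80 ± 0.34) and Trhr (3.75 ± 0.40, 19.7 kb). Other regions that fell were nearest to Cdyl (-2.97 ± 0.33), Gm21297 (-2.88 ± 0.30), Emc3 (-2.77 ± 0.30), Vps33b (-2.71 ± 0.28) and Dntt (-2.65 ± 0.32), where another region rose.

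In all, 11905 regions rose and 9480 fell with age in Pbx1 libraries, and 10795 and 10717 with total counts as the scaling. They lay within 1 kb of a gene end with odds ratios of 0.61 and 0.56. The count of 21385 was 13561 without young Pbx1 replicate 1. The age effects in mock and in Pbx1 libraries, which share no library, had r = 0.69 and rho = 0.62 across regions. Of the called regions, 5174 rose in both where chance gives 666, 3793 fell in both where chance gives 429, and 2 were called in opposite directions.

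At gene level, 2101 genes rose and 1900 fell with age in Pbx1 libraries. Of 23 HSC identity genes, 16 rose and none fell (17 adjusted over the list alone), with Hoxb5, a marker of long-term HSC, at 0.98 ± 0.15, Mpl at 0.71 ± 0.11 and Pdzk1ip1 at 0.63 ± 0.081. Of 26 Hox and TALE genes, 14 rose and none fell (15 adjusted over the list alone), with Hoxb6 at 0.95 ± 0.14 and Hoxa5 at 0.80 ± 0.15. These 2 lists had adjusted p of 8.14e-08 and 3.75e-07, and held with an estimated correlation (adjusted p = 0.0215 for both). Of 30 HSC ageing genes, 12 rose and none fell (13 adjusted over the list alone), with Clca3a1 at 1.69 ± 0.23, Cavin2 at 1.12 ± 0.13 and Aldh1a1, an aldehyde dehydrogenase, at 0.98 ± 0.091 (list adjusted p = 3.15e-07, and adjusted p = 0.0966 with an estimated correlation). Without old Pbx1 replicate 2, where these genes deviated by a median log2 of 0.17, the list had an adjusted p of 1.19e-05. Of 19 megakaryocyte genes, 5 rose and none fell (7 adjusted over the list alone), with Tubb1 at 1.08 ± 0.14 and Clec1b at 1.06 ± 0.32 (list adjusted p = 0.00705, and adjusted p = 0.295 with an estimated correlation). Clec1b did not pass without young Pbx1 replicates 1 or 3 or old Pbx1 replicate 2 (adjusted p up to 0.144).

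Of 22 NF-kB genes, 8 rose and 1 fell with age in Pbx1 libraries (10 and 1 adjusted over the list alone), with Ccl3 at 0.79 ± 0.11, Bcl3 at 0.74 ± 0.080 and Tnfaip3 at 0.44 ± 0.12 (list adjusted p = 0.000760, and adjusted p = 0.295 with an estimated correlation). With regions within 5 kb only Ccl3 had the opposite sign (-0.14, adjusted p = 0.775), and Tnfaip3 did not pass without young Pbx1 replicate 1 or old Pbx1 replicate 2 (adjusted p up to 0.0648). Of 20 AP-1 genes, 9 rose and 1 fell (10 and 2 adjusted over the list alone), with Nr4a1, an immediate early nuclear receptor, at 0.46 ± 0.092, Junb at 0.45 ± 0.066 and Maff at 0.42 ± 0.075 (list adjusted p = 0.00284, and adjusted p = 0.312 with an estimated correlation). Without old Pbx1 replicate 2, where both lists stood high (median log2 deviations of 0.22 and 0.20), they had an adjusted p of 0.0292 and 0.0213. Of 19 interferon genes, 6 rose and none fell (7 adjusted over the list alone), with Ifit1 at 1.03 ± 0.18, Oas1a at 0.46 ± 0.16 and Ifit2 at 0.43 ± 0.076 (list adjusted p = 0.00516, and adjusted p = 0.0675 with an estimated correlation). Ifit1 did not pass with the nearest gene end (adjusted p = 0.058), nor Oas1a in 10 of 12 omissions (up to 0.220), with regions within 5 kb (0.0514) or with the replicate block (0.0566). Of 20 TGF-beta and BMP genes, 9 rose and 3 fell (12 and 4 adjusted over the list alone), with Bmpr1a at 1.84 ± 0.13, Bmpr2 at 0.49 ± 0.10 and Skil at 0.37 ± 0.070 (list adjusted p = 0.00531, and adjusted p = 0.201 with an estimated correlation).

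The other 6 lists did not pass with age in Pbx1 libraries. The erythroid list passed with regions within 5 kb only (adjusted p = 0.0397), with the nearest gene end (0.0234) and without young Pbx1 replicate 3 (0.0422) or old Pbx1 replicate 3 (0.0289). Mcpt8 fell by 1.88 ± 0.25 among 13 mast cell genes, where 3 rose and 4 fell by either adjustment (list adjusted p = 0.499), with Prss34 at -0.71 ± 0.25 and Ms4a2 at 0.42 ± 0.13. Ctsg fell by 1.62 ± 0.27 and Mpo by 0.86 ± 0.20 among 22 neutrophil genes, where 1 rose, Spi1 at 0.29 ± 0.063, and 3 fell by either adjustment (list adjusted p = 0.499, median 0.0062 with a test pointing down). Cd3e, a subunit of the T cell receptor complex, fell by 1.11 ± 0.21, Bcl11b, a T cell transcription factor, by 0.58 ± 0.15 and Cd19, a B cell marker, by 0.58 ± 0.16 among 19 lymphoid genes, where 3 rose and 5 fell (4 and 6 adjusted over the list alone, list adjusted p = 0.449). Mcm6 fell by 0.66 ± 0.086, Mcm5 by 0.51 ± 0.071 and Mcm2 by 0.41 ± 0.091 among 27 cell cycle genes, where 3 rose and 9 fell (6 and 9 adjusted over the list alone, list adjusted p = 0.145). Of 16 erythroid genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone, list adjusted p = 0.0663), with the globin gene Hbb-bt at 0.48 ± 0.096, Epor at 0.46 ± 0.068 and Car2 at 0.33 ± 0.084. Of 15 stroma genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.499, median -0.0096 with a test pointing up), with Emcn at 0.84 ± 0.14, Col1a2 at 0.57 ± 0.097 and Pecam1 at 0.37 ± 0.080. Col1a2 did not pass with regions within 5 kb only (0.13, adjusted p = 0.640). Of the genes named here, Cd19 did not pass without old Pbx1 replicate 3 (adjusted p = 0.0685) and Prss34 in 5 of 12 omissions (up to 0.116). Ms4a2 did not pass in 3 and had 0.15 (adjusted p = 0.219) without old Pbx1 replicate 2. Of the 40 called members that the rule names for this comparison, 34 passed in every omission.

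**Figure D4:**
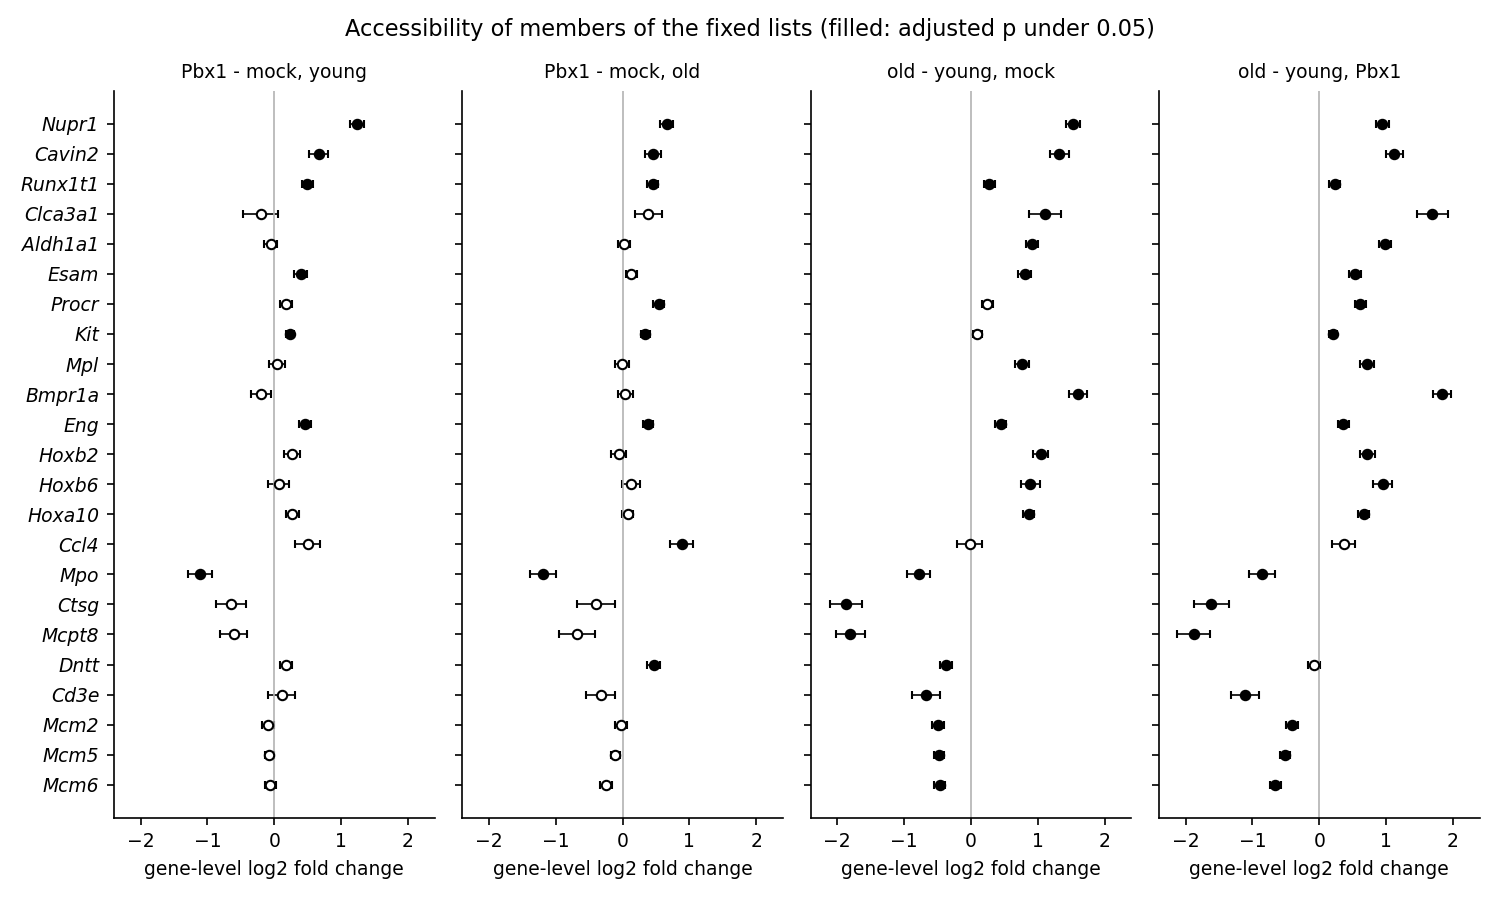
Log2 fold change ± SE of 23 genes of the fixed lists (vertical) in 4 comparisons of 2 groups with 3 libraries each, filled where the adjusted p was under 0.05. Nupr1 was higher and Mpo lower with Pbx1 at both ages.

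The Pbx1 effect in old HSC was also set against the age effect at the same regions, which asks whether added Pbx1 moved old chromatin towards young. Of the 13887 regions called for age in mock libraries, 869 rose with age and with Pbx1, and 188 fell with both. A further 166 fell with age and rose with Pbx1, and 26 rose with age and fell with Pbx1. Independent calls would give 209, 34.8, 169 and 43.0 regions, in this order. Both comparisons use the old mock libraries with opposite signs, so the calls are not independent and these are no chance levels. The shared libraries alone gave a covariance of -0.043 in simulations with no Pbx1 effect. The data gave 0.024, with a jackknife SE of 0.033 over omissions of 1 library, so that its own sign is not settled. The Pbx1 effect went against the age effect at 38.8% of the 13887 age-called regions. The simulations gave 64.3%, but over a mean of 25706 regions called for age per simulation, so these shares are not over the same regions. With that many calls their spread may differ from that of the libraries, which leaves the simulated covariance uncertain too. The covariance was 0.0051, 0.0031 and 0.0084 without old mock replicates 1, 2 and 3, 0.039 without old Pbx1 replicate 1 and 0.016 without old Pbx1 replicate 3, each with the shared libraries still in both comparisons. The 8 simulations took the fitted means as true, and the 3 old mock libraries were not split between the comparisons. In young HSC, where the shared young mock libraries raise the covariance, it was 0.096 against 0.060 simulated. There 1073 regions rose with both, where independent calls would give 190, but the shared libraries make these calls dependent too.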

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

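All tests in this part were planned before their result was seen, except the look at which labels the splits exchanged and the reading of the gene splits in the last sentence. The region of Arfgef1 stood out because the fold change with Pbx1 differed between ages by the test of the difference itself, with a log2 difference of -1.64 between old and young HSC (adjusted p = 0.00803). The rise in CPM was of similar size at both ages. The level of this region was already higher in old mock (10.6 CPM) than in young mock libraries (2.38 CPM), and all libraries with Pbx1 lay above all mock libraries of their age. The difference did not pass without young mock replicate 1 (adjusted p = 0.25), young Pbx1 replicate 3 (0.058) or old mock replicate 2 (0.066), or with cyclic loess and voom (0.095). Of 40 splits of the libraries within age, drawn from 200, 4 gave at least 1 region, counting the real one (1 region), so that this count did not exclude chance. The other 3 gave 1, 1802 and 10539 regions. In each, Pbx1 and mock labels were exchanged mostly or wholly in 1 age and at most for 1 Pbx1 library in the other, which puts the Pbx1 effect into the difference. This is a structure of the libraries, so the 3 splits are no clean measure of chance either. For genes the real split gave 0 calls in edgeR (1089 at an unadjusted p under 0.05), a count that all 40 splits reached, which by the planned share would not exclude chance and was read, after it was seen, as no test of chance.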

How the results depend on the processing

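Settings chosen only after the data were seen were thinning, the covariate, regions without overlap, autosomes only and the nearest gene end. Counts below are for Pbx1 in young HSC, Pbx1 in old HSC, age in mock and age in Pbx1 libraries, in this order, and the cause of a change was not tested unless stated. With only the groups compared, the spread was estimated from those libraries alone. The called regions were then 6285 in young HSC (3944 in the main fit) and 2068 in old HSC (4499), and the interaction has no value. Both Pbx1 counts thus depend on the 1 estimate of the spread that all groups share in the main fit. Thinned to the smallest library, they were 2287, 1850, 7899 and 11959, since depth is lower. An adjusted p under 0.01 gave 1920, 1821, 6654 and 11454 by construction, and a log2 fold change of at least 1 in size gave 2149, 2177, 6683 and 10568. A mean of at least 20 counts, which tests fewer regions, gave 2985 in old HSC and 9215 and 12084 for age, with r = 0.59 between Pbx1 effects and 0.80 between age effects. The difference between ages passed at 2 regions with total counts, 0 with cyclic loess, 10 with DESeq2, 21 with the replicate block, 2 without overlap, 7 with the covariate and 2 on autosomes. Estimated correlation left 0, 0, 2 and 2 lists.

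With the replicate number as a block, the called regions were 4933, 5948, 14768 and 21475, the genes 633, 891, 2769 and 3996 and the lists 4, 4, 8 and 8. The labels do not pair libraries by number. In old HSC, deviations of mock and Pbx1 libraries with the same number nevertheless correlated with r of 0.053, 0.151 and 0.115, each the highest for its library. Old libraries of different number gave -0.130 to 0.0101. In young HSC the same number gave 0.030, -0.0046 and -0.026, and different numbers gave -0.038 to 0.033. A pairing of the old libraries thus stays open, and the main test of old HSC uses none. With regions within 5 kb only, Col1a2 (-0.11, from 0.45) and Ccl3 (-0.18, from 0.48) with age in mock and Ccl3 (-0.14, from 0.79) in Pbx1 libraries had the opposite sign. Motif tests, with both of their alternatives, were not run for lack of a genome sequence.

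Without 1 library at a time, the called regions ranged from 2126 to 6482, 1680 to 6647, 7827 to 19344 and 13561 to 22490, and the difference between ages from 0 to 21. Genes ranged from 198 to 1091, 166 to 1015, 1445 to 3923 and 2691 to 4207, and lists from 0 to 5, 2 to 7, 6 to 8 and 8 to 9. The correlation of Pbx1 effects ranged from 0.38 to 0.43, that of age effects from 0.62 to 0.69, the covariance of Pbx1 in old HSC with age from 0.0031 to 0.039 and the percentage against the age effect from 36.5 to 43.0. At the Pbx1 gene the log2 fold change ranged from -0.090 to 0.0082, -0.0011 to 0.28, 0.046 to 0.15 and 0.14 to 0.42. Of the values for named genes under other settings, 584 of 619 kept direction and side of the threshold, 25 no longer passed, 7 newly passed and 3 changed sign. Of those for named regions, 388 of 389 did so and 1 no longer passed. These counts leave out the omissions of 1 library. Under the omissions, 164 of 1488 values for named genes no longer passed and 11 newly passed. For named regions 10 of 780 no longer passed. Of the called members that the rule names for Pbx1 against mock, 4 of 15 in young and 9 of 16 in old HSC passed in every omission.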

Other observations

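Tests chosen only after the result was seen were those of depth at the X-linked loci and of a trend on level in old Pbx1 replicate 2. The thinned and covariate settings were also chosen after the data were seen. The other tests of explanations were set before their result was seen. The test of genes with many called regions was not among the planned tests, and the genes named from it are examples. Some genes held more called regions than their number of regions gives by chance. In young HSC these included Fstl4 (6 of 21 regions rose with Pbx1, 0.459 by chance, adjusted p = 0.00272) and Sox5, a transcription factor gene (8 of 61, 1.33 by chance, adjusted p = 0.0166). In old HSC they included Gpi1, which encodes glucose-6-phosphate isomerase (7 of 11, 0.266 by chance, adjusted p = 2.87e-06), and Dym (9 of 41, 0.992 by chance, adjusted p = 0.000320). Sox5 did not pass in old HSC (5 of 61, 1.48 by chance, adjusted p = 0.930). With age, 16 of 29 regions of Rnf220, a ubiquitin ligase gene, fell in mock libraries (1.27 by chance, adjusted p = 2.59e-11) and 18 in Pbx1 libraries (1.93 by chance). Cdk6, a cell cycle kinase gene, had 14 of 53 regions that fell with age in Pbx1 libraries (3.53 by chance, adjusted p = 0.00237), but 6 in mock libraries (2.33 by chance, adjusted p = 1), which did not pass. Regions of 1 gene are not independent, so these p values are too small to an unknown degree.

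Firre, Xist and the Dxz4 locus had higher counts in every old library. The tables argue against depth as the source, since after thinning to 1 total the lowest old library was still 2.94 times the highest young one or more at each locus. A candidate explanation is that the old mice were female and the young mice male, which is a hypothesis. Near 6 genes known to escape X inactivation (11 regions), the median log2 fold change of old against young was 0.53 above that of 776 other X-linked regions in mock and 0.43 above it in Pbx1 libraries; the 6 called regions all belong to Eif2s3x, Kdm5c and Ddx3x, while Mid1 (-0.25 in mock and -0.47 in Pbx1), Utp14a (0.012 and -0.16) and Pbdc1 (2 regions, -0.33 and 0.22 in mock, 0.43 and 0.40 in Pbx1) did not pass. Age, gate, pooling of mice and sex would move together in all libraries and cannot be told apart from each other in this design.

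Old Pbx1 replicate 2 stood apart from the other old Pbx1 libraries. Each old sample came from 1 mouse, so a difference between mice stays open, and 1 library gives no test of that. A trend on the mean level of a gene accounted for 0.572% of the variance of this library's deviation. The level of a gene sum also follows its number of regions, so this trend does not decide on signal over background. In this library 36.2% of counts lay near gene ends, the lowest share of all libraries, against 36.6% and 38.5% in the other old Pbx1 libraries. Heat shock genes may account for part of this library's deviation. Without Hspa1a (2.28), Hspa1b (1.53) and Hsp90aa1 (0.87), which prompted the test, 18 of them had a median log2 deviation of 0.24. That median lay at percentile 99.99 of 10000 random lists of like level. Hspd1 (2.13) and Hspb1 (1.73) were the highest of the 18, while Bag3 (-0.0087), Chordc1 (-0.029), Stip1 (-0.035) and Hspa2 (-0.041) were slightly negative. Other lists also stood high, with NF-kB at 0.22 (percentile 99.99), HSC ageing at 0.17 (99.96) and AP-1 at 0.20 (99.94), and the cell cycle stood low (percentile 1.96). Cells of another type stay open, since the highest of 6 lists of other cell types, the erythroid one, had a median of 0.15, between the bounds set for either answer, although the sort removed lineage-positive cells.

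More regions rose than fell with Pbx1, and added Pbx1 itself is the biological explanation the design gives. With every library thinned to the smallest, at least 84.9% of the called regions rose at either age, which argues against depth. With the share of counts near gene ends as a covariate, at least 80.0% rose, which argues against that share as the source. For scaling, the share fell to 71.6% in old HSC with total counts, which met the bound of 70% set beforehand. It exceeds that bound by less than the SD over omissions of 1 library (2.41 in old and 3.06 in young HSC). This margin was not part of the bound as first written, and with it scaling stays open.

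Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The called regions were 3944, 4499, 13887 and 21385 for Pbx1 in young, Pbx1 in old, age in mock and age in Pbx1 libraries, and the highest other split called 0 in each, as for genes, where 1 split of 10 gave as many. The called lists were 3, 3, 8 and 8, and the highest other splits called 5, 7, 8 and 8. As many lists were called by 4, 7, 2 and 3 of the 10 splits. A list call with the preset correlation therefore does not by itself set the real groups apart from other splits. Each other split exchanges 1 library of each group, so it keeps part of the real difference and adds the rest to the spread. The counts of the other splits are thus no clean measure of chance, for regions, genes or lists.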
